A study of Mus musculus with 7 samples.

How the data were processed

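RNA-seq was made from amygdala neurons of male C57BL/6J mice. An adeno-associated virus (AAV) carrying a guide RNA against Nr2f2 (sgNr2f2, 3 libraries) or against the Rosa locus as a control (sgRosa, 4 libraries) was delivered to the amygdala, with Cas9 under the hSyn (synapsin) promoter, per the labels and the series description. After expression the mice were restrained in tubes on 7 days, were fear conditioned for 1 day and then had 3 days of extinction, per the labels' protocols. Per the same protocols, the tissue was digested with papain, neurons were taken with a magnetic neuron isolation kit, and 5 ng of total RNA went into each library. All 7 libraries come from stressed mice, so the series holds no unstressed group. The labels do not say whether each library came from 1 animal or from a pool, and p-values measure the spread between these libraries.

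The authors deposited raw counts per gene symbol, in 1 file per library and in 1 table of the whole series, and the 7 single-library files held the same values as the table. The deposited counts were whole numbers that no normalization had touched. The submitters' processing notes name fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, STAR 2.7.5c, featureCounts 2.0.1 and edgeR 3.42.4 and the genome build mm10. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap or have near-identical copies can therefore have exchanged reads: Nr2f2, for example, overlaps the annotated transcript B130024G19Rik. The files held 35976 gene symbols, of which 11650 had no count in any library. A RefSeq table of the GRCm38.p6 assembly matched 32501 symbols (90.3%), which held 98.1% of all counts, and gave the coordinates printed here. Total counts ran from 6266897 to 20928677 per library. No molecular identifiers are named in the labels, and PCR reads without them are not independent molecules, so count-based floors cover counting error only.

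Differential expression was computed from the counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, edgeR's filter on low counts (14412 genes kept) and the group as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given as CPM (counts scaled to a common library total) on TMM-scaled library sizes, as mean ± SD over 4 sgRosa and 3 sgNr2f2 libraries, and fold changes as sgNr2f2 against sgRosa. Log2 CPM used a prior count of 2. Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry. These tests used log2 CPM and took nothing from edgeR's fit. In fits by DESeq2 the lists were tested with camera's pre-ranked form on DESeq2's gene statistics, and in fits by limma-voom with camera on voom's values. List results that differ between tools therefore also differ in the test or its input. Of 47 lists written down before the data were examined, 46 had at least 5 measured members and were tested. They cover cell type markers, receptors and channels, neuropeptides, stress and immune responses, metabolism and axon guidance. Library measures and list scores were compared with an exact two-sided permutation test over the 35 splits of the 7 libraries, whose smallest possible p is 0.02857.

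The genes named in the text follow a rule fixed together with the lists. It takes Nr2f2, its paralogs Nr2f1 and Nr2f6, and Ptprk and Egfr in every case. It takes the 12 largest rises and the 12 largest falls among genes past the adjusted threshold that have an official-style symbol, a mean of at least 20 counts and groups that do not overlap, and fills empty places with the genes of smallest p that meet the other conditions. It also takes up to 4 members with the smallest p from each list called by camera or holding a member past the adjusted threshold. No gene passed, so all 24 leading places were filled by smallest p. Some genes that the rule takes are not reported here. Any gene named outside the rule is marked as chosen after its values were seen.

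The fit was checked on simulated counts drawn from the real gene means, library sizes and dispersions, with 200 genes changed and 13887 genes tested. With the spread of these 7 libraries, edgeR recovered 1.49% of genes changed 2-fold, 7.46% of those changed 4-fold and 50% of those changed 8-fold. DESeq2 recovered 2.99%, 47.0% and 81.8% and also called 47 unchanged genes, against 3 by edgeR. camera called the list shifted 2-fold in the simulation and no other. Genes were drawn independently there, whereas the estimated correlation within the called lists of the real data ran from 0.087 to 0.74. The simulation therefore cannot show how often camera calls unshifted lists in these data. Libraries of a group were also drawn alike, so none stood apart as sgRosa replicate 4 does in the real data. The recovered shares and the false calls may thus not carry over to the real data, where DESeq2 called 7 genes in all.

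Alternatives covered other scaling factors, low-count filters, DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersions, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a non-neuronal marker score as a covariate, counts without mitochondrially encoded genes, and each library left out in turn. Fits without sgRosa replicate 4 by the other tools, and fits with a correction for GC content, were added after the data were seen. The correction used a loess curve per library on the GC content of each symbol's longest GENCODE M21 transcript, which 94.2% of tested genes had. Figures were drawn with matplotlib 3.10.9.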

Results

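The data were gene counts from 7 RNA-seq libraries of neurons isolated from the mouse amygdala after restraint stress, fear conditioning and fear extinction. They bear on the role of Nr2f2 (COUP-TFII, a nuclear receptor transcription factor) in amygdala neurons under chronic stress, although much of the RNA came from other cells. Of the 7 libraries, 4 carried the control guide sgRosa and 3 the guide sgNr2f2. The total counts of sgRosa replicates 1 to 4 were 15335076, 19788953, 17546894 and 6266897. Those of sgNr2f2 replicates 1 to 3 were 18112558, 16497269 and 20928677. Between 16364 and 19916 genes had at least 1 count in a library.

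Oligodendrocyte transcripts made up a large part of most libraries, although the isolation was meant to keep neurons. Mbp, which encodes myelin basic protein, alone took 14.4 ± 10.5% of counts in sgRosa (n = 4) and 21.1 ± 6.01% in sgNr2f2 (n = 3), and the 19 oligodendrocyte markers together took 2.73 to 32.4% per library. Mitochondrially encoded transcripts took 13.5 ± 3.04% and 10.8 ± 1.92%. The libraries of the groups overlapped in both shares (exact permutation p = 0.371 for Mbp and 0.286 for mitochondrial transcripts, adjusted p = 0.65 for each within 14 library measures), which does not show that the shares were equal. sgRosa replicate 4 stood apart from the other 6 libraries. It had the lowest total, 1.47% Mbp, and 3.77% of counts in erythroid genes against 0.125 to 0.348% in the others. Its mean correlation with the other libraries was 0.72, against 0.88 to 0.90 for the rest, and it lay alone on a first principal component that held 52.3% of the variance.

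**Figure D1:**
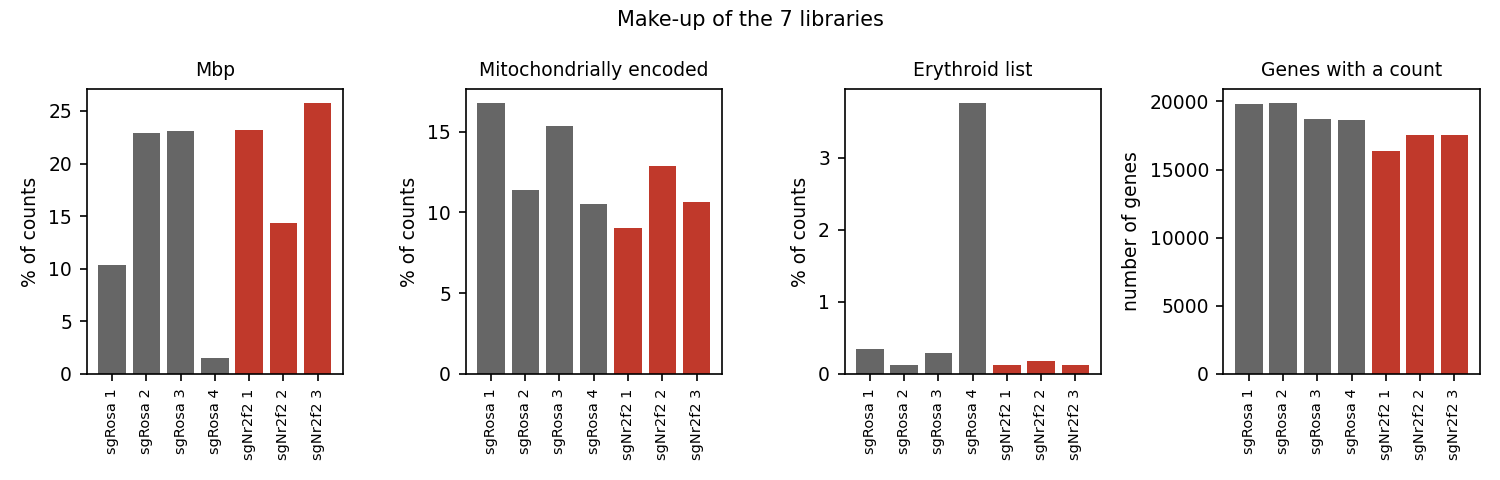
Share of counts (%) taken by Mbp, by mitochondrially encoded genes and by the erythroid list, and the number of genes with at least 1 count, 1 bar per library, sgRosa in grey and sgNr2f2 in red. sgRosa replicate 4 has the lowest Mbp share (1.47%) and the highest erythroid share (3.77%), and the 3 sgNr2f2 libraries have the fewest genes detected.

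The targeted gene, Nr2f2 (chromosome 7, 70351946 to 70366746, mm10), had 422, 305, 166 and 96 counts in sgRosa replicates 1 to 4 and 196, 214 and 191 in sgNr2f2 replicates 1 to 3. Its level was 15.2 ± 3.76 CPM in sgRosa (n = 4) and 11.8 ± 0.22 CPM in sgNr2f2 (n = 3). The log2 fold change was -0.36 with an SE of 0.37 and a 95% confidence interval from -1.19 to 0.47, and it did not pass (edgeR adjusted p = 0.905, exact permutation p = 0.257). It was -0.21 without sgRosa replicate 1. Cas9 edits change the genomic sequence and need not lower the transcript count, so these counts neither show nor exclude editing. How much of the Nr2f2 count came from neurons was not measured. The paralogs Nr2f1 and Nr2f6 had log2 fold changes of -0.68 (SE 0.76) and 0.27 (SE 0.49). Over the fits that left out 1 library that of Nr2f1 ran from -1.04 (without sgNr2f2 replicate 3) to 0.27 (without sgRosa replicate 4) and that of Nr2f6 from 0.075 (without sgRosa replicate 1) to 0.71 (without sgRosa replicate 4). Ptprk, a receptor tyrosine phosphatase, lay at 17.7 ± 4.33 and 17.6 ± 2.61 CPM.

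Comparing sgNr2f2 with sgRosa asks which transcripts differ when Nr2f2 is targeted in stressed mice. The stress hormone-responsive gene Fkbp5, an immunophilin that dampens glucocorticoid receptor signalling, was the gene with the smallest p. It lay at 11.3 ± 7.90 CPM in sgRosa and 97.7 ± 49.1 CPM in sgNr2f2, a log2 fold change of 3.11 (SE 0.65), and was higher in each sgNr2f2 library than in any sgRosa library. Neither it nor any other gene passed edgeR's test: 0 of 14412 genes were higher and 0 lower (smallest adjusted p = 0.868). At an unadjusted p under 0.05 there were 314 genes higher and 407 lower, 721 in all, against 720.6 expected by chance. Scaling by library size alone gave 127 and 621, and upper-quartile factors 245 and 541. DESeq2 called 1 gene higher, Fkbp5, and 6 lower, and limma-voom called 0. Without sgRosa replicate 4, an alternative added after the data were seen for tools other than edgeR, edgeR still called 0 genes (904 higher and 688 lower at an unadjusted p under 0.05), limma-voom called 0, and DESeq2 called 225 higher and 119 lower.

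**Figure D2:**
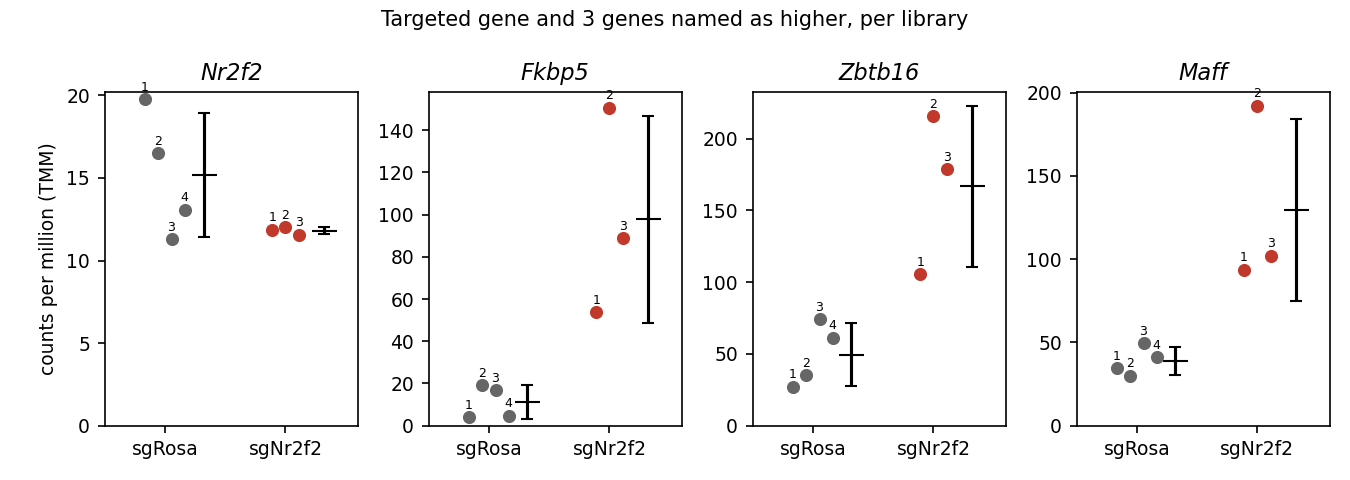
TMM-scaled CPM of Nr2f2, Fkbp5, Zbtb16 and Maff in each library, sgRosa in grey and sgNr2f2 in red, numbered by replicate, with the mean and SD of each group as a black bar. Nr2f2 values of the groups overlap (15.2 ± 3.76 and 11.8 ± 0.22 CPM), whereas each sgNr2f2 library lies above all sgRosa libraries for the other genes. The naming rule required this of Fkbp5 and Maff.

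The 12 leading genes on the higher side did not pass edgeR's adjusted test. Each was higher in all 3 sgNr2f2 libraries than in all 4 sgRosa libraries, but this was a condition of naming them and not a result. After Fkbp5 (chromosome 17, 28398753 to 28486149) they included the transcription factor Maff at 38.8 ± 8.45 and 129.3 ± 54.6 CPM (log2 fold change 1.74, SE 0.43) and the histone H3K27 demethylase Kdm6b at 27.1 ± 8.45 and 80.2 ± 19.8 CPM (1.57, SE 0.41). Mknk2, which encodes a kinase of the translation factor eIF4E, had a log2 fold change of 1.73 (SE 0.43), and Cables1 lay at 8.03 ± 3.90 and 34.2 ± 13.2 CPM. The log2 fold changes of Midn, Tmem151b, Cnnm4, Coro2a, Tcf23, the cation channel gene Trpv4 and the Polycomb-associated gene Phf19 ran from 1.57 for Tmem151b to 3.67 for Phf19, the latter from 0.27 to 3.16 CPM. That of Phf19 was 4.43 without sgRosa replicate 4, and that of Coro2a went from 2.01 to 1.29 without sgNr2f2 replicate 2.

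The 12 leading genes on the lower side likewise did not pass edgeR's adjusted test and lay lower in all 3 sgNr2f2 libraries, which the naming rule required. DESeq2 called 3 of them, Gpx8, Cyp2f2 and Bmp5, and without sgRosa replicate 4 it called 11 of these 12 and all 12 on the higher side. These genes were picked by p from the same libraries, so the DESeq2 calls are no separate support. Gpx8 lay at 4.96 ± 5.14 and 0.30 ± 0.17 CPM, Rspo3, a secreted activator of Wnt signalling, at 5.54 ± 4.63 and 0.64 ± 0.39 CPM, and the proprotein convertase Pcsk5 at 6.67 ± 1.31 and 2.00 ± 0.24 CPM. Without sgRosa replicate 2 the sgRosa mean was 2.40 CPM for Gpx8 and 3.27 CPM for Rspo3. The heparan sulfate proteoglycan gene Sdc2 lay at 32.0 ± 9.88 and 11.5 ± 2.04 CPM. Bmp5, a bone morphogenetic protein, had 161 counts in sgRosa, of which 136 were in replicate 2, and 0 in sgNr2f2, which was at least 44.2-fold lower against a floor of 3 counts over the group, and at least 9.77-fold lower without sgRosa replicate 2. Cyp2f2 had 146 counts, 104 of them in sgRosa replicate 2, and 0 in sgNr2f2 (at least 40.0-fold lower, and at least 16.4-fold without that library). Outside these 12, Egfr, the epidermal growth factor receptor gene, had 71 counts, 44 of them in sgRosa replicate 2, and 0 in sgNr2f2 (at least 19.5-fold lower, and at least 10.6-fold without that library), but sgRosa replicate 4 also had 0. The floor covers counting error only, so the folds given for Bmp5, Cyp2f2 and Egfr are not firm lower bounds. As a class, low-level genes were more often at 0 in sgNr2f2. At equal depth 20.9 to 33.6% of 2675 such genes were at 0 there, against 5.83 to 15.8% in sgRosa. Whether this accounts for the zeros of Bmp5, Cyp2f2 and Egfr was not tested. The clock output gene Dbp lay at 36.9 ± 16.1 and 11.5 ± 3.07 CPM, and Ndnf, a marker of neurogliaform interneurons, at 16.2 ± 9.27 and 4.17 ± 1.85 CPM. Hacd4, Nat8f4 and Itgb3bp were also among the 12, with log2 fold changes from -2.23 for Hacd4 (-1.53 without sgRosa replicate 4) to -1.79 for Nat8f4. Groups that do not overlap were counted for 635 genes on the higher side and 562 on the lower, against 411.8 expected by chance on each side (5.71% on both together). Genes measured in the same libraries are not independent and the spread of this expectation was not computed, so the counts do not show an excess.

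As groups, gene lists leaned more often lower than higher in sgNr2f2. camera at its preset correlation called 15 of 46 lists, 2 higher and 13 lower, relative to the other genes, whose median log2 fold change was -0.11. With an estimated correlation camera called 0 lists (adjusted p = 0.883 for each of the 15), and fry called 0 (smallest adjusted p = 0.917). Called lists numbered 6 without sgRosa replicate 4 and 5 without sgNr2f2 replicate 2. Only the GABA receptor, monoamine and acetylcholine receptor and oxidative phosphorylation lists were called in all 7 fits that left out 1 library. With limma-voom quality weights the calls of both receptor lists ended too (camera adjusted p = 0.0661 for each), and only 4 of the 15 stayed called, the ribosomal, mitochondrial, oxidative phosphorylation and pericyte and smooth muscle lists. With 1 surrogate variable 9 stayed called, without the oligodendrocyte, channel, glutamate receptor, interneuron and axon guidance lists.

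The glucocorticoid response list was higher in sgNr2f2, with 15 of its 19 measured members on the higher side (camera adjusted p = 0.00701, and adjusted p = 0.883 with an estimated correlation). Some other splits of the libraries also called it. Camera adjusted p was 0.00713 for sgRosa replicate 2 with sgNr2f2 replicates 2 and 3 against the rest. It was 0.0134 for sgRosa replicate 3 with the same 2 libraries and 0.0234 for sgRosa replicates 1, 3 and 4. Each other split that called the list put 2 or 3 sgNr2f2 libraries with 1 sgRosa library, so it kept much of the real contrast. Some splits of that kind did not call it. Adjusted over the list alone, 2 members passed edgeR's test, Fkbp5 (adjusted p = 0.0127) and Zbtb16, a zinc finger transcription factor (adjusted p = 0.0473), and 0 passed over all genes. Zbtb16 lay at 49.5 ± 21.9 CPM in sgRosa and 166.7 ± 56.0 CPM in sgNr2f2. The cyclin-dependent kinase inhibitor Cdkn1a lay at 238.0 ± 86.2 and 559.0 ± 253.2 CPM and the lipid droplet gene Plin4 at 3.24 ± 2.58 and 8.54 ± 5.24 CPM (log2 fold change 1.39, and 2.11 without sgRosa replicate 2), and neither passed. The list was not called without sgNr2f2 replicate 2 (camera adjusted p = 0.148) or with limma-voom quality weights (0.107, median log2 fold change 0.07, 12 of 19 members higher), and its median log2 fold change went from 0.34 to 0.06 without sgRosa replicate 4, with 13 of 19 members on the higher side (camera adjusted p = 0.0474). Its score, the median z-score of its members, gave an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.809 over 46 list scores. The oligodendrocyte list was the other list called higher (18 of 19 members, camera adjusted p = 0.0217, and adjusted p = 0.883 with an estimated correlation). None of its members passed over the list alone, and the call ended without sgRosa replicate 1 or 4 (camera adjusted p = 0.1003 and 0.601) and without sgNr2f2 replicate 1 or 3 (0.491 and 0.140). Its leading members Mal, Cnp, Fa2h and Mag had log2 fold changes from 0.63 to 0.94, from 0.47 to 0.60 without sgRosa replicate 4, from 0.19 to 0.78 without sgNr2f2 replicate 1, from 0.91 to 1.73 without sgRosa replicate 2 and from 0.85 to 1.45 without sgNr2f2 replicate 2. That of Mag was 0.40 without sgNr2f2 replicate 3.

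Lists of neuronal receptors and peptides lay lower. All 14 GABA receptor genes were on the lower side (camera adjusted p = 3.773e-04, and adjusted p = 0.883 with an estimated correlation), with 0 passing over the list alone. Without sgRosa replicate 4 these were 11 of 14 (camera adjusted p = 0.0474), and on log2 CPM the call ended with a GC correction as well (0.159). It stayed without that library with DESeq2 (0.00205), limma-voom (0.0237) and DESeq2 with the GC correction (0.0213). Gabra3 lay at 18.8 ± 9.49 CPM in sgRosa and 8.19 ± 2.91 CPM in sgNr2f2 and Gabrg3 at 13.6 ± 15.1 and 3.99 ± 2.32 CPM, with 36.0 CPM in sgRosa replicate 4 and a log2 fold change of -1.75 that was -0.61 without it. Of the 27 neuropeptide and stress peptide receptor genes 25 were on the lower side (camera adjusted p = 2.343e-06, and adjusted p = 0.883 with an estimated correlation). Crh, which encodes corticotropin-releasing hormone, had 0, 1 and 10 counts in sgNr2f2 replicates 1 to 3 and a log2 fold change of -3.89 (SE 1.44). Without sgNr2f2 replicate 3 it was -6.51, a value that rests on 1 count in sgNr2f2 and does not show a stronger fall. The sgRosa mean of Crh was 3.423 CPM, and 1.57 CPM without replicate 4. The gene of its binding protein, Crhbp, lay at 7.83 ± 8.99 and 0.76 ± 0.49 CPM (log2 fold change -3.32, and -2.14 without sgRosa replicate 4), Nts at 11.1 ± 9.57 and 1.96 ± 0.46 CPM and Npy1r at 5.43 ± 0.88 and 2.42 ± 0.18 CPM. The sgRosa mean of Nts rested on replicates 1 and 4 (20.4 and 18.3 CPM). sgRosa replicates 2 and 3 had 2.22 and 3.54 CPM, and the groups overlapped. The call of this peptide list ended without sgRosa replicate 4 on log2 CPM (camera adjusted p = 0.0733), but not with DESeq2 (0.0319), limma-voom (0.0496) or a GC correction (0.0311). Of 19 monoamine and acetylcholine receptor genes, 16 were on the lower side (camera adjusted p = 1.707e-04, and adjusted p = 0.883 with an estimated correlation). Drd5, Htr1a, Chrm2 and Htr4 led it at mean levels of 0.90 to 6.56 CPM in sgRosa and 0.08 to 1.56 CPM in sgNr2f2, and none passed over the list alone. As a class, genes of 0.5 to 2 CPM had a lower mean count in sgNr2f2 at equal depth (4.336 to 4.847, against 5.169 to 7.575 in sgRosa). Whether low-level members of these lists lay lower beyond that was not tested. The 4.31 ± 7.67 CPM of Htr4 in sgRosa rested on replicate 4, without which it was 0.47 CPM, and the log2 fold change of Chrm2 went from -2.05 to -0.95 without that library.

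Voltage-gated potassium channels (19 of 23 members on the lower side), glutamate receptors (18 of 21), sodium and calcium channels (19 of 23) and markers of interneurons from the medial ganglionic eminence (9 of 11) were also called lower, with camera adjusted p-values of 0.00953, 0.0113, 0.0393 and 0.0311. With an estimated correlation the adjusted p was 0.883 for each. The potassium channel score was 1.58 in sgRosa replicate 4 and -0.43 to 0.32 in the other libraries, and without that library none of these lists was called (camera adjusted p = 0.382, 0.560, 0.853 and 0.382), nor without sgNr2f2 replicate 2 (0.148, 0.254, 0.16 and 0.139). The sodium and calcium channel call also ended without sgRosa replicate 1 (0.0581) and sgNr2f2 replicates 1 (0.0654) and 3 (0.0565), the glutamate receptor call without sgNr2f2 replicate 3 (0.0565) and the interneuron call without sgNr2f2 replicate 1 (0.0585). Without a low-count filter the sodium and calcium channel and interneuron calls ended, and with limma-voom the former. Members with the smallest p were Kcnb2, Kcnc4, Kcnd3 and Kcnh7 among potassium channels, Grm5, Grm2, Gria1 and Grik1 among glutamate receptors, and Scn3b, Cacna2d1, Scn3a and Scn1a among sodium and calcium channels. Among interneuron markers, Sst, the somatostatin gene, lay at 45.5 ± 38.4 and 14.6 ± 1.96 CPM, Nxph1 at 17.1 ± 6.28 and 6.77 ± 3.10 CPM, and Sox6 and Tac1 had log2 fold changes of -1.13 and -1.24. Without sgRosa replicate 4 the log2 fold change of Sst went from -1.64 to -0.93 and that of Tac1 to -0.43. None of these members passed, and the log2 fold changes of Kcnc4, Kcnd3, Gria1, Grik1, Scn3b, Cacna2d1 and Scn1a went from between -1.88 and -1.06 to between -1.03 and -0.53 without sgRosa replicate 4.

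Lists of small housekeeping transcripts lay lower by less. The median log2 fold change was -0.52 over 75 nuclear genes of oxidative phosphorylation (64 lower, camera adjusted p = 6.460e-04) and -0.33 over 79 cytosolic ribosomal protein genes (66 lower, camera adjusted p = 0.00623). The adjusted p was 0.883 for both with an estimated correlation. The oxidative phosphorylation score was 1.76 in sgRosa replicate 4 and -0.62 to 0.44 in the other libraries, and without that library the list's median was -0.15 with 55 of 75 lower (camera adjusted p = 0.0373). Atp5k lay at 37.1 ± 10.8 and 15.1 ± 4.18 CPM, Atp5e at 38.7 ± 7.00 and 20.3 ± 3.81 CPM, Rps21 at 54.7 ± 17.6 and 25.0 ± 1.69 CPM and Rps27 at 165.2 ± 73.5 and 73.2 ± 2.64 CPM, and Ndufb2, Ndufa5, Rpl37a and Rpl38 followed with log2 fold changes from -1.21 to -1.04, of which those of Ndufa5 and Ndufb2 were -0.69 and -0.61 without sgRosa replicate 4. Of 12 mitochondrially encoded genes 11 were on the lower side (camera adjusted p = 0.0418, and adjusted p = 0.883 with an estimated correlation). ND3 lay at 28.6 ± 5.24 and 12.2 ± 3.10 CPM, whereas the other leading members ATP6, COX2 and COX3 had only 1.01 to 2.60 CPM in sgRosa (0.63 to 1.72 CPM without sgRosa replicate 3), far under the 11905 CPM of COX1, and their counts are uncertain. The ribosomal call ended without sgRosa replicate 2 or 3 (camera adjusted p = 0.1045 and 0.1595) and without sgNr2f2 replicate 2 (0.519), and the mitochondrial call without sgRosa replicate 2 or 3 (0.0786 and 0.591) and without sgNr2f2 replicate 1 or 2 (0.2755 and 0.148).

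Erythroid markers and pericyte and smooth muscle markers were called lower, whereas 10 of 18 endothelial markers were on the higher side and that list was not called (camera adjusted p = 0.242). All 10 erythroid genes were on the lower side (camera adjusted p = 0.00623, and adjusted p = 0.883 with an estimated correlation), with Hbb-bt, Hba-a1 and Hbb-bs among its leading members. Hba-a1 lay at 3066 ± 5158 CPM in sgRosa and 320.1 ± 43.8 CPM in sgNr2f2, and its log2 fold change was -3.26 with sgRosa replicate 4 and -0.61 without it. Those of Hbb-bt and Hbb-bs went from -2.16 and -2.64 to -1.05 and -0.86. All 13 pericyte and smooth muscle markers were on the lower side (camera adjusted p = 0.0311, and adjusted p = 0.883 with an estimated correlation), with Vtn, Myl9, Acta2 and Higd1b at log2 fold changes from -1.73 to -1.23, from -1.37 to -0.69 without sgRosa replicate 4 and from -2.55 to -1.98 without sgNr2f2 replicate 1. Without sgRosa replicate 4 the camera adjusted p on log2 CPM was 0.0557 for erythroid genes and 0.0733 for pericyte and smooth muscle markers. It was 0.00450 and 0.00620 with DESeq2, 0.0375 and 0.0496 with limma-voom, and 0.0291 and 0.0130 with a GC correction. The erythroid call also ended without sgNr2f2 replicate 2 (0.0813), and the pericyte and smooth muscle call without sgRosa replicate 2 or 3 (0.266 and 0.0807) and sgNr2f2 replicate 2 or 3 (0.254 and 0.118). The axon guidance list was called lower (26 of 38 members, camera adjusted p = 0.0460, and adjusted p = 0.883 with an estimated correlation), although its leading members went both ways. The receptor gene Robo1 lay at 6.01 ± 1.83 and 1.87 ± 0.17 CPM and its ligand gene Slit2 at 10.7 ± 2.09 and 4.76 ± 1.39 CPM, whereas the semaphorin receptor gene Plxna2 lay at 70.0 ± 22.2 and 241.7 ± 131.9 CPM and Sema7a at 25.8 ± 13.6 and 81.1 ± 32.2 CPM. None passed over the list alone, and the list was called only without sgRosa replicate 2 or 3 among the 7 fits that left out 1 library. Its camera adjusted p was 0.298 and 0.175 without sgRosa replicates 1 and 4 and 0.190, 0.148 and 0.0565 without sgNr2f2 replicates 1 to 3, and it was not called with limma-voom, upper-quartile or library size scaling, or without a low-count filter.

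The remaining 31 lists were not called, with camera adjusted p-values from 0.0536 for the circadian clock to 0.935 for heat shock and dissociation genes. They included excitatory neuron, inhibitory neuron and central amygdala markers, astrocyte, microglia and endothelial markers, and interferon, complement and cytokine genes. For immediate early genes camera's direction was higher while the median log2 fold change was -0.23 (camera adjusted p = 0.903), and Maff alone passed edgeR's test when adjusted over the list alone (adjusted p = 0.0438).

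Several named genes overlap other genes in the annotation. Whether reads were shared was not measured, and their counts are uncertain because the counting's strand and multi-mapping settings are not given in the sources used here. Dbp overlaps Sphk2, Hacd4 overlaps Focad, Gpx8 overlaps Cdc20b, Tmem151b overlaps Tcte1, Plin4 overlaps Hdgfl2 and Cnp overlaps Dnajc7. The globin genes and the ribosomal protein genes belong to families with near-identical copies.

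The groups also differed in the GC content of the genes on either side and in the number of genes detected. Of 303 genes with a GC value on the higher side at an unadjusted p under 0.05, 47.5% lay in the highest of 5 equal GC bins of tested genes (from 55.6% GC) and 8 in the lowest bin. Of 383 on the lower side, 60 lay in the highest bin and 104 in the lowest. In sgRosa 19256 ± 691.1 genes had a count (n = 4) and in sgNr2f2 17156 ± 686.2 (n = 3), with all 3 sgNr2f2 libraries under all 4 sgRosa libraries (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.2). Genes with at least 10 counts numbered 13789 ± 1120.9 and 13775 ± 131.7. These numbers were not taken at equal depth. sgRosa replicate 4, with the lowest total, had 12215, and sgRosa replicates 1 to 3 had 14493, 14681 and 13766. The sgNr2f2 libraries had 13626 to 13876.

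**Figure D3:**
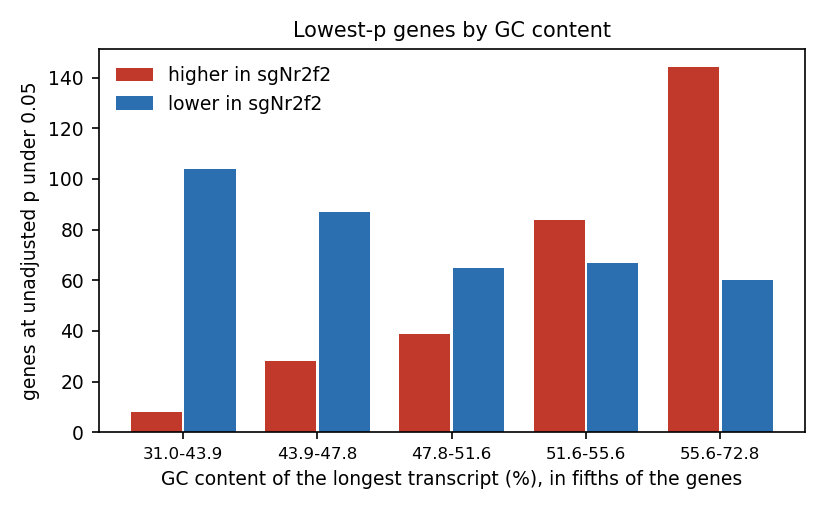
Number of genes at an unadjusted p under 0.05 in edgeR's test, higher or lower in sgNr2f2, in 5 equal bins of the tested genes ordered by GC content of the longest transcript. The number on the higher side goes from 8 in the lowest bin to 144 in the highest, and on the lower side from 104 to 60.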

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

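In groups of 4, a library is named here when its gap to the nearest other library exceeds Dixon's 95% critical share of the group's range, which only the sgRosa group was large enough to test. Chance flags about 1 in 20 groups. Of 144 measures 11 met this, against 7.2 expected, and 7 of the 11 concern sgRosa replicate 4. No explanation is weighed for them.

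In sgRosa replicate 4 the erythroid share of counts was 3.77% (0.129 to 0.348% in the other sgRosa libraries) and the mean correlation with the other libraries was 0.7225 (0.8813 to 0.9004). Its score for central amygdala and striatal GABAergic markers was 1.37 (-0.18 to -0.0052), for glycolysis 1.56 (-0.42 to -0.38) and for the proteasome 1.97 (-0.32 to -0.22). Its log2 CPM was 5.55 for Sdc2 (4.71 to 4.80) and 3.99 for Htr4 (-0.99 to -0.54).

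In sgRosa replicate 2 the choroid plexus score was 1.17 (-0.95 to -0.59), and log2 CPM was 3.68 for Gpx8 (1.10 to 1.51). The ribosomal protein score was -0.97 in sgRosa replicate 1 (0.54 to 0.81). With equal depth and without myelin and mitochondrial genes, sgRosa replicate 3 had 17775 genes detected (18579 to 18641).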

How the results depend on the processing

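Fits with a GC correction, and fits by DESeq2 or limma-voom without sgRosa replicate 4, were chosen after the data were seen. edgeR and limma-voom called 0 genes under each alternative run, with and without sgRosa replicate 4. DESeq2 called 1 gene higher and 6 lower, 225 higher and 119 lower without sgRosa replicate 4, and 88 higher and 58 lower with the GC correction as well. The cause was not tested, and in data simulated for all 7 libraries DESeq2 also called 47 unchanged genes, whereas fits without sgRosa replicate 4 were not simulated. No simulated library stood apart as sgRosa replicate 4 did, so the 47 may not carry over to the real libraries.

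Lists called numbered 15, and 5 with limma-voom quality weights, 9 with 1 surrogate variable, and 0 with an estimated correlation, which counts the correlation between members. More were called with DESeq2 (17), library size only (17), the stricter filter (16) and the non-neuronal score as a covariate (18). Without sgRosa replicate 4 there were 9 with limma-voom, 7 with the GC correction, 11 with DESeq2 and 12 with DESeq2 and the GC correction. Leaving out 1 library gave 5 (without sgNr2f2 replicate 2) to 18 (without sgRosa replicate 1). The sodium and calcium channel list turned direction with quality weights (camera adjusted p = 0.868, range 2.319e-04 to 0.853 over the fits that left out 1 library). The cause was not tested.

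The Nr2f1 log2 fold change was 0.62 with quality weights, 0.20 with the surrogate variable, and 0.29 with DESeq2 and 0.06529 with limma-voom, both without sgRosa replicate 4. Leaving out 1 library gave -1.04 to 0.27. The Htr4 log2 fold change was 0.39 with quality weights, 0.16 with the surrogate variable and 0.25 with DESeq2 without sgRosa replicate 4. The causes of these turns were not tested beyond the fits without sgRosa replicate 4. The Ptprk log2 fold change, -0.02 over all libraries, ran from -0.18 to 0.11 over the fits that left out 1 library. Over 87 named results, 2049 of 2120 alternative values kept direction and side of the threshold, 57 passed it and 14 turned direction. Over the 15 lists 261 of 389 kept both, 127 lost the call and 1 turned direction.

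With the replicate number as a block, 5 lists were called (not oxidative phosphorylation, camera adjusted p = 0.05097), the Nr2f1 log2 fold change was 0.16 and the Htr4 log2 fold change 0.20. Libraries with the same number did not deviate together (correlations of -0.20, -0.26 and 0.09), so the numbers were not read as pairs, and the cause was not tested. The median log2 fold change of all genes was -0.11 with TMM, -0.33 with library size only and -0.31 with DESeq2. Robust dispersions do not enter camera, whose list results are then those without them.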

Other observations

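Tests of the GC pattern, of sgRosa replicate 4 for the glucocorticoid list and of library size for the genes detected, and the count of lists over splits without sgRosa replicate 4, were chosen after the results were seen, as were the fits with a GC correction and the fits by DESeq2 without sgRosa replicate 4. The test on silent genes was added after the result of the test on distinct molecules had been seen. The genes named in the next paragraph were chosen after their values were seen, apart from Maff, Dbp and Ndnf.

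Members of some lists that were not called went apart. Among immediate early genes Maff was on the higher side, whereas Fos lay at 364.2 ± 235.2 CPM in sgRosa and 107.8 ± 52.6 CPM in sgNr2f2, Egr1 at 249.2 ± 287.0 (107.2 without sgRosa replicate 1) and 51.9 ± 19.8 CPM and Egr3 at 34.6 ± 23.5 and 9.83 ± 5.40 CPM, and none of these passed edgeR's test. Among astrocyte markers Gfap lay at 47.6 ± 44.3 (25.8 without sgRosa replicate 2) and 129.2 ± 23.6 CPM and Fgfr3 had a log2 fold change of 1.495 (0.86 without sgNr2f2 replicate 2), whereas Slc1a2 had -0.81 (-1.35 and -0.36 without sgNr2f2 replicates 1 and 2) and Aqp4 -1.07 (-0.50 without sgRosa replicate 2 and -1.65 without sgNr2f2 replicate 3). Among clock genes Dbp was on the lower side, whereas Per2 and Bhlhe40 had log2 fold changes of 1.00 (-0.22 without sgNr2f2 replicate 2) and 0.95 (0.60 without sgRosa replicate 4 and 0.58 without sgNr2f2 replicate 2). Among markers of interneurons from the caudal ganglionic eminence, Ndnf, Sncg and Calb2 were on the lower side (camera adjusted p = 0.0704 for the list), but the log2 fold changes of Sncg and Calb2 were -0.55 and -0.11 without sgRosa replicate 4. The microglial receptor gene Cx3cr1 lay at 1.48 ± 1.17 CPM in sgRosa, with none in replicate 4. In sgNr2f2 it lay at 0.0561 to 0.0606 CPM, near the lowest level that can be counted. The microglia list had 7 members higher and 12 lower and was not called (camera adjusted p = 0.908).

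Genes on the higher side were GC-rich and those on the lower side GC-poor. That sgRosa replicate 4 alone made this is argued against: without it the correlation of log2 fold change with GC over genes was 0.3788, against 0.0441 with it. GC-dependent differences between libraries stay open and may account for it: sgRosa replicate 4 differed from the mean of sgRosa replicates 1 to 3 with a Spearman correlation of 0.4135, against 0.36 for the sgNr2f2 mean. That rests on 1 library, since sgRosa replicates 1 to 3 differed among themselves by -0.02 to 0.05. An effect of targeting Nr2f2 was not tested apart from this and also stays open.

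The glucocorticoid response list lay 0.57 (SE 0.22 over members) above the median gene on the log2 scale. The SE over members treats genes of the same libraries as independent and does not measure the spread between libraries. The list mean lay 0.55 (SE 0.20) above the median gene without sgRosa replicate 4 and 0.61 (SE 0.21) with the oligodendrocyte score as a covariate. This argues against that library and the oligodendrocyte share as the whole cause of the mean, led by Fkbp5 and Zbtb16. After GC correction of all libraries the mean lay 0.55 (SE 0.23) above. Log2 fold change hardly followed GC there before correction (Spearman correlation 0.0441), so that fit cannot decide on GC. Without sgRosa replicate 4 the correlation was 0.3788, and the correction took the mean from 0.55 to 0.47 (SE 0.19). GC stays open as part of the cause. The median member lay 0.45 above and 0.09483 without sgRosa replicate 4, so that library stays open as a cause for the typical member. With the GC correction and without sgRosa replicate 4 the mean lay 0.47 (SE 0.19) above. There the call ended with camera on log2 CPM (adjusted p = 0.0572) but not with camera's pre-ranked form on DESeq2's statistics (adjusted p = 0.00802). The call also ended without sgNr2f2 replicate 2, where the mean lay 0.37 (SE 0.24) above (camera adjusted p = 0.148). It ended too with limma-voom quality weights, where the mean lay 0.42 (SE 0.21) above (camera adjusted p = 0.107). A higher glucocorticoid response with sgNr2f2 is a hypothesis that may be followed up, and it rests in part on sgNr2f2 replicate 2 and is not called with an estimated correlation (adjusted p = 0.883). Some other splits of the libraries call the list as well (camera adjusted p down to 0.00713). Each of them puts 2 or 3 sgNr2f2 libraries with 1 sgRosa library and so is close to the real grouping.

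Fewer genes were detected in sgNr2f2. Library size is argued against, since at equal depth outside myelin and mitochondrial genes the lowest sgRosa library still had 1024 more than the highest sgNr2f2 library. Fewer distinct molecules in sgNr2f2 stay open: at equal depth 20.9 to 33.6% of 2675 genes of 0.5 to 2 CPM were at 0 in sgNr2f2 and 5.83 to 15.8% in sgRosa, and the median count above 0, which this explanation would raise, averaged 4.667 in sgNr2f2 (5 to 6 in sgRosa) but also falls with the genes' lower mean count there (4.34 to 4.85 against 5.17 to 7.57). Low-level reads over silent genes in sgRosa also stay open as a possible explanation: 1454 olfactory and vomeronasal receptor genes took 9.69 to 26.3 CPM in sgRosa and 5.07 to 8.50 CPM in sgNr2f2, a gap of 1.186 CPM between the nearest libraries, but the numbers of them with a count overlapped (18 to 73 and 11 to 20). A biological difference was not tested apart from these.

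Chance could not be excluded for the counts over all 7 libraries. As many genes at an unadjusted p under 0.05 came from 13 of the 35 splits of the libraries (721, highest other split 2245), as many lists from 13 (15, highest other 24), and as many DESeq2 calls from 8 (7, highest other 418). Any split reaches the adjusted edgeR count of 0, so the 35 that did (highest other 0) say nothing about chance. Splits that call several times the real count point to a structure of the samples, and the highest placed sgRosa replicates 1 and 4 with sgNr2f2 replicate 2. Without sgRosa replicate 4 there are 10 splits, too few for a share under 0.05: 1 of 10 gave as many DESeq2 calls (344, highest other 67), 1 of 10 with the GC correction (146, highest other 54), and 9 of 10 as many lists (6, highest other 20).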
